A study of Homo sapiens with 48 samples.

How the data were processed

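Chromatin accessibility was measured by ATAC-seq, in which the transposase Tn5 inserts sequencing adapters into open chromatin, in primary human macrophages grown from blood monocytes of 4 donors, called A to D here. Cells received 1 of 7 stimuli, or none, for the first 24 hours of culture. They were then washed, rested and harvested on day 6 or day 11, with 100000 cells per library, per the labels' protocols. The series holds 48 libraries in 24 groups of 2, each group being 1 donor, 1 stimulus and 1 day. Groups and replicate numbers were taken from the titles. The labels do not say whether the 2 libraries of a group came from separate cultures, so within a donor p-values then measure only the spread between these samples, which may be technical.

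Each of the 4 deposited tables holds raw counts, whole numbers per merged peak and library with no normalization. The unit was read from the values, which are whole and sum to different totals in each library, and from the table names. Peaks were merged separately in each table: day 6 of donors A, B and C (24 libraries), days 6 and 11 of donor A (16), TGFb and the other groups of donor C (10), and donor D (14). The day 6 libraries of donor A and the libraries of donor C other than TGFb appear in 2 tables, so those results are not independent of the comparison over 3 donors. Bowtie2, Picard and MACS2 and the genome build hg38 are named, with no versions, per the submitters' processing notes. The counting program, the read filters, any shift of read ends for the Tn5 offset, and whether reads or fragments were counted are not given in the sources used here. Merging peaks over all libraries of a table gives every library the same intervals, but a peak open in few libraries rests on few counts in the others. Values were compared only within a table, and tables were set side by side only through fold changes.

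The tables hold 91476, 97509, 61389 and 103746 peaks in the order above. Peaks on chromosome Y and within 50 kb of XIST or TSIX (19, 17, 7 and 10 peaks) were left out. Chromosome 22 was not analysed here. Median peak width was 353, 348, 338 and 350 bases. No reference genome was used, so the planned tests of sequence motifs and the correction for GC content were not run. Peaks were placed with gene coordinates of the RefSeq table of assembly GRCh38.p14, the same build as hg38, which gives gene spans without strand, exons or transcription start sites. A peak was assigned to the gene whose span holds its midpoint, or else to the nearest gene end within 50 kb. In place of a distance to the start site, a peak was called near a gene end when its midpoint lay within 1 kb of either end of a protein-coding gene. That departs from the plan, and exons, introns and UTRs cannot be told apart. Of the peaks, 53.8%, 53.6%, 53.7% and 54.9% lay inside a gene, 32.1%, 31.6%, 33.6% and 31.4% outside but within 50 kb, and 14.1%, 14.8%, 12.7% and 13.8% had no gene. An assignment to a gene is by position, and does not show which gene a peak acts on.

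Counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, TMM scaling, all groups of a table in 1 fit, two-sided), after filterByExpr with a minimum count of 10 and a minimum total of 15. Benjamini-Hochberg adjustment ran over the peaks tested, and a peak was called at an adjusted p below 0.05. For the 3-donor table the 2 libraries of each donor and stimulus were summed, which gave 12 summed libraries and a fit with donor as covariate (85122 peaks tested, 6 residual degrees of freedom, biological coefficient of variation 0.11). The single-donor tables were fitted by group (91738, 48108 and 94167 peaks, with 8, 5 and 7 residual degrees of freedom and coefficients of 0.0507, 0.0451 and 0.0604). Levels are CPM (counts per 10 to the power of 6, with TMM-scaled library totals), and log2 fold changes carry the standard error |log2 fold change| / sqrt(F). The day interaction in donor A was the difference of 2 log2 fold changes in the same fit. Donor dependence was the donor by stimulus term in a fit of the 24 unsummed libraries.

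The comparisons, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. There are 18 lists. The 9 pathway lists are IFN-gamma response, type I IFN-stimulated genes, MHC class II, inflammatory cytokines and NF-kB feedback, pattern recognition receptors, glycolysis and HIF targets, cholesterol synthesis, lipid handling and LXR targets, and TGF-beta and SMAD targets. The 3 cell type lists are monocyte, macrophage and monocyte-derived dendritic cell genes. The 6 lists of other cell types are T cell, B cell, NK cell, platelet and megakaryocyte, neutrophil and erythroid genes. Some genes sit in 2 lists, such as CIITA (IFN-gamma response and MHC class II), APOE, APOC1 and MSR1 (lipid handling and macrophage), CD14 (pattern recognition and monocyte) and MARCO (pattern recognition and macrophage). All peaks assigned to a list's genes were tested against the other peaks with camera (limma 3.58.1) at a preset correlation of 0.01, and again with an estimated correlation. The family is 468 tests, 18 lists in 26 comparisons, of which 82 passed and 56 passed with an estimated correlation; adjusted p-values are within a comparison. The share of called peaks near a gene end was compared with that of the other tested peaks by Fisher's exact test (78 tests, Benjamini-Hochberg).

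Named peaks follow a fixed rule. The largest rises and falls are called, assigned to a protein-coding gene within 50 kb, at a mean log2 CPM of 1 or more, and changed the same way in all 3 donors, or, within a donor, with both libraries on the same side of both controls. The condition on single libraries was not set for differences between days. List members were taken by their p alone. For each stimulus against untrained cells in 3 donors the 8 genes of largest rise and 8 of largest fall were taken, with the 2 member peaks of smallest p of each pathway and cell type list. In other comparisons these were 5 and 5, with the member peak of smallest p of each list that passed. The rule gave 411 entries, or 406 different pairs of peak and comparison, some of which the text leaves out. Members named beside a list count without a value are those with a called peak.

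Against a group with no counts a fold is a lower bound from a floor of 3 counts over the group. With 1 to 3 counts the ratio of scaled counts is given with its exact 95% interval (for differences between days, that of Fisher's exact test on the 4 summed counts). These intervals and floors cover counting error only, since PCR copies are not independent molecules. Total counts ranged from 0.479 to 6.46 M (M, 10 to the power of 6) per library in the 3-donor table (median 3.03), 2.83 to 6.5 in donor A (4.47), 0.939 to 3.21 in donor C (2.1) and 3.42 to 10 in donor D (5.79). Replicates differed by more than sampling noise (chi-square per degree of freedom 1.06 to 2.15), and no library was counted as a copy of another.

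The fits were tested on simulated data drawn from the real means and library sizes, with 200 peaks changed 1.25, 1.5, 2 or 4-fold. Over 82694 simulated peaks of the 3-donor table, the shares recovered were 0%, 6%, 42% and 84% for beta-glucan, 0%, 12%, 46% and 86% for MDP and 0%, 16%, 52% and 86% for IFNg. For TGFb against untrained cells they were 0%, 8%, 22% and 70% (45481 peaks). In donor D they were 0%, 6%, 38% and 76% for CpG and 0%, 20%, 58% and 82% for oxLDL (90806 peaks), and in donor A at day 11 they were 2%, 10%, 28% and 78% for beta-glucan (84444 peaks).

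Alternatives were DESeq2 1.42.0 (Wald test), DESeq2 size factors in edgeR, scaling by total count, trended loess offsets (span 0.3), no low-count filter, a test against a 1.2-fold change (glmTreat), only the groups compared, no donor covariate, 24 unsummed libraries, limma-voom with duplicateCorrelation, the replicate number as a block, and leaving out each donor or library in turn. For lists they were 1 peak per gene, peaks near gene ends and an estimated correlation; for positions, 2 kb in place of 1 kb and an overlap of 1 base in place of 50% between tables. Fits without the library of lowest depth, without the library farthest from its replicate, with peaks assigned to the nearest gene end, and between stimuli in donor A were added after seeing the data. Overlaps of comparisons that share controls were set beside 10 (3 donors), 8 (donor A) and 6 (donor D) simulations of unchanged groups. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.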

Results

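The series asks whether different stimuli, given to human monocytes for 24 hours at the start of culture, leave different marks on chromatin days after the stimulus has gone. Accessibility was measured in 48 libraries. At day 6, donors A, B and C each gave 2 libraries of untrained cells and 2 after beta-glucan (a fungal cell wall sugar polymer, 5 µg/mL), MDP (in macrophage work usually muramyl dipeptide, a bacterial cell wall fragment sensed by NOD2, 1 µg/mL) and IFNg (interferon gamma, 50 ng/mL). Donor A gave the same groups again at day 11. Donor C added TGFb (transforming growth factor beta, 2 ng/mL). Donor D added oxLDL (oxidised low density lipoprotein, 10 µg/mL), CpG (a TLR9 ligand, 100 ng/mL) and polyIC (a mimic of double-stranded RNA, 10 µg/mL). Depth over peaks ran from 0.479 M counts (M, 10 to the power of 6) in donor B's untrained replicate 2, where 23.2% of peaks had no count, to 10 M in donor D. Below, levels are CPM as mean ± SD, changes are log2 fold changes ± SE, and adjusted p-values are from edgeR unless a list is tested.

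Beta-glucan left more accessible chromatin at inflammatory and MHC class II genes 5 days after it was washed out, although as lists both missed the threshold with an estimated correlation (adjusted p = 0.102 with an estimated correlation). The peak inside IL1B, the interleukin-1 beta cytokine gene (chromosome 2, 112830099 to 112830491), stood at 15.2 ± 8.68 CPM in trained cells and 2.01 ± 0.419 in untrained cells of the 3 donors, a log2 change of 2.83 ± 0.344 (adjusted p = 2.71e-05). The peak 600 bases outside NAMPT, which encodes an enzyme of NAD synthesis (chromosome 7, 106247100 to 106248296), changed by 2.91 ± 0.545 (7.59 ± 5.19 against 1.18 ± 0.583 CPM). The peak outside NFKBIA, an inhibitor of NF-kB (chromosome 14, 35399011 to 35400649), changed by 1.65 ± 0.184 (127 ± 84.3 against 40.2 ± 24.5 CPM, adjusted p = 9.21e-06), and the peak beside CCL4, a chemokine gene with a near copy next to it, by 1.46 ± 0.171. At HLA-DQA1, an MHC class II chain (chromosome 6, 32637167 to 32637548), the change was 2.59 ± 0.316 (8.35 ± 3.49 against 1.43 ± 0.585 CPM); HLA genes vary and resemble each other, so peaks there are uncertain. The largest rises also held PIGU (3.23 ± 0.404), ADPRH, which lies next to the costimulator gene CD80 (3.12 ± 0.551), APTX, SSPN, RFTN1 and OGFRL1 (2.69 to 3.09). The largest falls were at FHIT (-2.39 ± 0.426), FAM135B, ERLIN2, MAGI2, ANKRD30BL, EBLN1, MAST2 (4.54 ± 3.17 against 15.5 ± 9.06 CPM) and TIMM21 (-1.75 ± 0.266).

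Of the 30 measured genes of the inflammatory list, 22 had only higher peaks called after beta-glucan, 1 (IL10) only lower and 7 none. Over its 228 peaks 61 were higher and 1 lower (98 and 3 adjusted over the list alone), with a median of 0.51 (adjusted p = 6.08e-18, and adjusted p = 0.102 with an estimated correlation). In the MHC class II list 9 of 12 genes rose and 3 had no call, with 13 of 70 peaks higher (20 adjusted over the list alone) and a median of 0.39 (adjusted p = 2.79e-10, and adjusted p = 0.102 with an estimated correlation). The IFN-gamma response list rose through CD274, ETV7, ICAM1 and IRF1, 4 of 25 genes, with 9 of 127 peaks higher (16 adjusted over the list alone, median 0.19, adjusted p = 0.000735, and adjusted p = 0.102 with an estimated correlation). IRF1, an interferon-induced transcription factor, changed by 1.17 ± 0.142 at a peak 41937 bases from it, and ICAM1, an adhesion molecule, by 0.93 ± 0.134. Pattern recognition receptors had 9 higher of 169 peaks (12 higher and 1 lower adjusted over the list alone, adjusted p = 0.0235, and adjusted p = 0.155 with an estimated correlation), among them SYK, a kinase downstream of the beta-glucan receptor (1.17 ± 0.241), and CLEC4E (0.85 ± 0.193). Cholesterol synthesis had 6 higher of 79 (10 higher and 2 lower adjusted over the list alone, adjusted p = 0.00915, and adjusted p = 0.131 with an estimated correlation), among them INSIG1 (0.56 ± 0.102) and LSS (0.89 ± 0.177). The other lists did not pass. Dendritic cell genes had 8 higher and 1 lower peak (adjusted p = 0.0819) and TGF-beta and SMAD targets 13 and 8 (adjusted p = 0.945). Adjusted p-values were 0.277 for monocyte, 0.489 for macrophage, 0.886 for glycolysis and 0.489 for lipid handling genes. In type I IFN-stimulated genes the 2 called peaks, at OAS1 (-1.40 ± 0.339) and IFI6 (-0.91 ± 0.241), were lower (adjusted p = 0.886), and the median of 0.03 and the mean of -0.03 differ in sign. Lists of other cell types gave adjusted p-values of 0.945 (T cell), 0.277 (B cell), 0.459 (NK cell), 0.945 (platelet), 0.277 (neutrophil) and 0.82 (erythroid).

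In all, 1934 of 85122 tested peaks (2.27%) were called after beta-glucan, 1402 higher (median log2 change 1.03) and 532 lower (-0.94), and 1908 (98.7%) moved the same way in each donor. The peaks were called in these same donors, so the choice of peaks raises that share and it is no separate test. The count was 107 without donor C, 1142 without donor A and 2209 without donor B. DESeq2 called 1062, and the fit without a donor covariate 53.

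**Figure D1:**
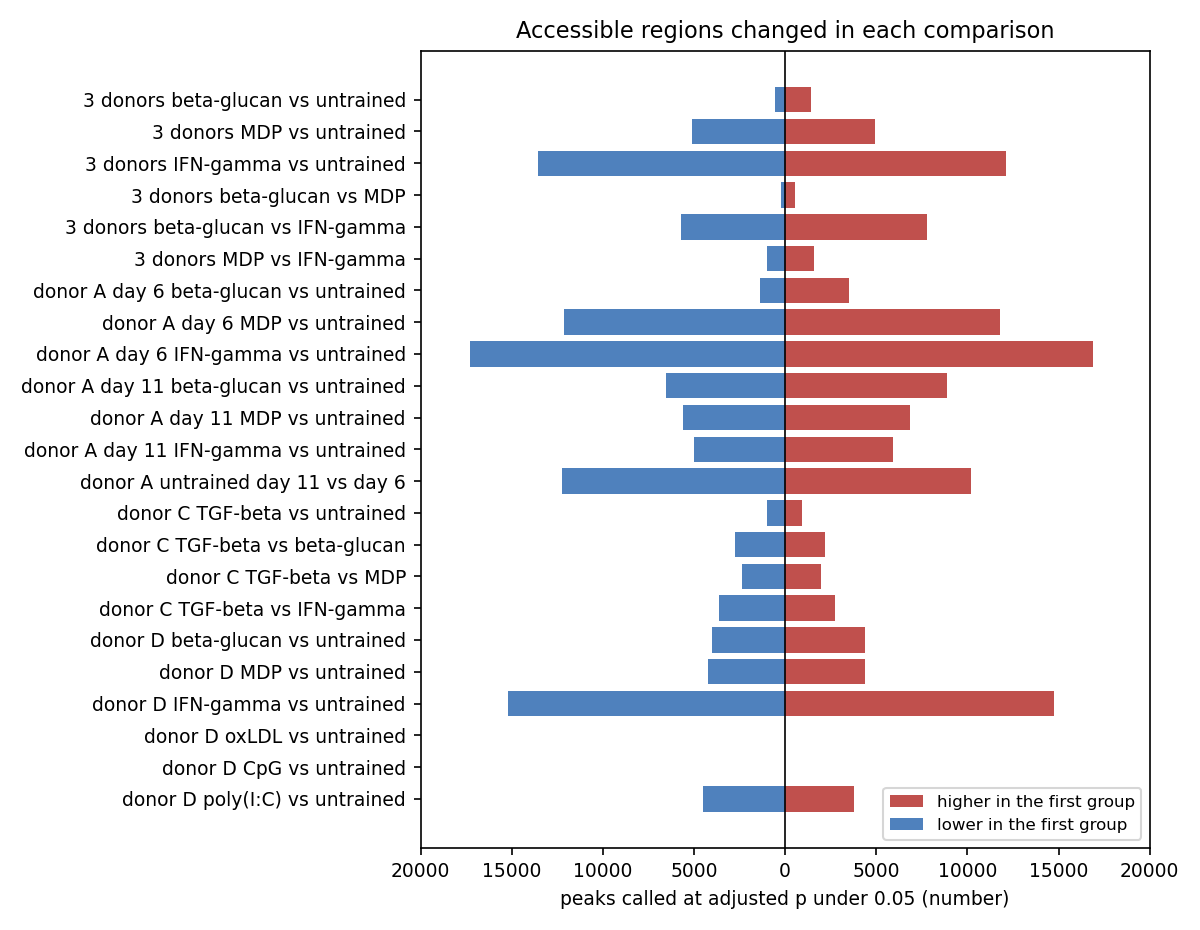
Number of peaks called higher and lower (horizontal bars, x axis in peaks) in each comparison (y axis). In 3 donors the calls number 1934 after beta-glucan, 10007 after MDP and 25652 after IFNg, and in donor D 22 after oxLDL and 11 after CpG.

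After MDP, inflammatory genes had gained accessibility (as a list, adjusted p = 3.05e-18, but adjusted p = 0.0946 with an estimated correlation), and a peak of the chemokine gene CCL22 had lost it. A peak 1161 bases outside EGR1, an immediate early transcription factor (chromosome 5, 138469833 to 138471096), rose from 5.89 ± 2.93 to 35.1 ± 13.7 CPM (2.67 ± 0.357, adjusted p = 2.25e-05, n = 3 donors). PTGS2, the inducible cyclooxygenase (chromosome 1, 186670900 to 186671572), changed by 2.69 ± 0.503 (3.14 ± 1.70 against 0.616 ± 0.148 CPM) and HLA-DQA1 by 2.72 ± 0.30. NFKBIA rose by 1.94 ± 0.181 to 142 ± 42.6 CPM (adjusted p = 3.93e-07), and a wide peak inside the chemokine gene CCL3 by 1.05 ± 0.112 (355 ± 76.8 against 176 ± 61.2 CPM). The CCL22 peak fell from 18.8 ± 8.24 to 7.24 ± 4.77 CPM (-1.46 ± 0.22). The largest rises were completed by SSPN (3.07 ± 0.386), PIGU, RFTN1, OGFRL1 and ZZEF1 (2.58 ± 0.361), and the largest falls were at LURAP1L (-3.09 ± 0.432), RPGRIP1, IKZF2 (1.79 ± 0.557 against 10.6 ± 5.47 CPM), NPSR1, CSTA, VTCN1, TLE7 and STAC (-2.39 ± 0.384).

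Inflammatory genes with only higher peaks numbered 19 of 30 after MDP, with 1 (IL1RN) only lower, 4 with both and 6 with none. Over its peaks 90 rose and 5 fell (121 and 11 adjusted over the list alone, median 0.56, adjusted p = 3.05e-18, and adjusted p = 0.0946 with an estimated correlation). MHC class II had 21 higher and no lower peak of 70 (28 adjusted over the list alone; 10 of 12 genes, median 0.55, adjusted p = 5.87e-11, and adjusted p = 0.0946 with an estimated correlation), HLA-DOA, a chain of the peptide-loading regulator, changing by 1.13 ± 0.142. The IFN-gamma response list had 15 higher and 2 lower peaks (16 and 3 adjusted over the list alone, median 0.17, adjusted p = 0.0119, and adjusted p = 0.113 with an estimated correlation). Pattern recognition receptors had 19 higher and 8 lower (21 and 9 adjusted over the list alone, adjusted p = 0.0191, and adjusted p = 0.157 with an estimated correlation), with rises at TLR1 (0.99 ± 0.128) and at NLRP3, the inflammasome sensor (1.10 ± 0.153). The remaining lists held called peaks without passing. Glycolysis had 15 higher and 8 lower (adjusted p = 0.27), with the glucose transporters SLC2A1 (1.60 ± 0.321) and SLC2A3 (1.06 ± 0.171) higher. Lipid handling had 11 and 8 (adjusted p = 0.638), with the lysosomal lipase LIPA lower (-1.04 ± 0.159) and SCARB1 higher (0.92 ± 0.123). TGF-beta targets had 35 and 21 (adjusted p = 0.599), with the receptor TGFBR1 at 1.13 ± 0.179. Type I IFN genes had 5 and 0 (adjusted p = 0.27), with CMPK2 (1.53 ± 0.351) and ISG20 (1.08 ± 0.193). The CMPK2 change was uneven, 2.54 in donor A, 0.846 in B and 0.0185 in C, while that of ISG20 was 1.05, 1.02 and 1.01. Macrophage genes had 8 and 7 (adjusted p = 0.873), with VSIG4 at 1.49 ± 0.357. Dendritic cell genes had 19 and 10 (adjusted p = 0.258), with CD80 at 1.01 ± 0.156. Cholesterol synthesis (6 and 6, adjusted p = 0.616) and monocyte genes (9 and 5, adjusted p = 0.0533) did not pass. Neither did T cell genes (2 and 7, adjusted p = 0.258), NK cell genes (3 and 3, adjusted p = 0.616) or the 4 other lists.

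MDP changed 10007 peaks (11.8%), 4906 higher (median 0.77) and 5101 lower (-1.04), and 9655 of them (96.5%) moved the same way in each donor, a share raised by calling the peaks in these donors. Without donor A the count was 2294 and without donor C 5132. DESeq2 called 4784, and scaling by total count split 9971 calls into 3497 higher and 6474 lower.

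IFNg left the most calls of the 3 stimuli, and MHC class II genes had the highest median change of the lists that passed. All 12 MHC class II genes had higher peaks and none a lower one: 47 of 70 peaks rose (51 adjusted over the list alone), with a median of 1.12 (adjusted p = 9.93e-17, and adjusted p = 0.0478 with an estimated correlation). HLA-DQA1 rose to 16.4 ± 9.25 CPM (3.51 ± 0.284, adjusted p = 2.49e-09, n = 3 donors), and a second HLA-DOA peak (chromosome 6, 33027894 to 33028134) from 1.15 ± 0.736 to 12.1 ± 3.30 CPM (3.31 ± 0.278). The peak inside TCOF1, the gene next to the MHC class II invariant chain gene CD74 (chromosome 5, 150398536 to 150400331), rose from 7.91 ± 3.47 to 80.2 ± 35.5 CPM (3.56 ± 0.319, adjusted p = 8.72e-09). IL1B rose by 3.41 ± 0.319 to 21.5 ± 7.99 CPM, NAMPT by 3.76 ± 0.487 and PTGS2 by 3.59 ± 0.472. C1QB, a complement chain made by macrophages (chromosome 1, 22652578 to 22653274), rose from 7.45 ± 0.515 to 32.1 ± 13 CPM (2.19 ± 0.215). Accessibility fell at MERTK, a receptor for the uptake of dying cells (-1.43 ± 0.141; 20.4 ± 5.05 against 53.0 ± 13.1 CPM), at CCL22 (-2.71 ± 0.255; 2.98 ± 0.0398 against 18.8 ± 8.24 CPM) and at COL4A1, a collagen gene (-2.56 ± 0.265). The largest rises also held ZNF331 (3.64 ± 0.449), ADPRH and VAC14 (3.39 ± 0.308). The largest falls were at SORCS1 (-4.81 ± 0.452; 0.29 ± 0.0907 against 7.17 ± 3.72 CPM), SNX2, COPG1, FHIT, FMN1, VPS36, XPNPEP2 and PRKCH (-3.77 ± 0.457).

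The IFN-gamma response list had 53 higher and 4 lower of 127 peaks after IFNg (57 and 5 adjusted over the list alone), with a median of 0.52 (adjusted p = 2.02e-08, and adjusted p = 0.0232 with an estimated correlation). Of its 25 genes 14 had only higher peaks, CXCL9 only lower, 3 both and 7 none. ICAM1 rose to 64.6 CPM and IRF1 changed by 1.42 ± 0.136. Inflammatory genes had 118 higher and 17 lower peaks (128 and 21 adjusted over the list alone, median 0.74, adjusted p = 8.24e-15, and adjusted p = 0.0869 with an estimated correlation), with NFKBIA at 2.17 ± 0.18 and TNFAIP3, a brake on NF-kB, at 1.86 ± 0.158. Pattern recognition receptors had 43 higher and 15 lower, over the whole set and adjusted over the list alone (median 0.27, adjusted p = 0.00503, and adjusted p = 0.0979 with an estimated correlation), and monocyte genes 26 and 7 on both counts (adjusted p = 0.0399, and adjusted p = 0.0796 with an estimated correlation), with FCN1 at 1.12 ± 0.159. Type I IFN genes did not pass (16 higher, 10 lower, adjusted p = 0.149), with ISG20 higher by 1.99 ± 0.185. Glycolysis had 36 and 18 (adjusted p = 0.262), with HIF1A at 0.75 ± 0.0961 and GPI at -1.75 ± 0.175. Cholesterol synthesis had 17 and 7 (adjusted p = 0.149), with INSIG1 at 0.96 ± 0.0997. Dendritic cell genes had 39 and 20 (adjusted p = 0.0763), with CD80 at 1.57 ± 0.154. Lipid handling (20 and 33), TGF-beta targets (59 and 66) and macrophage genes (20 and 25) each had adjusted p = 0.94, the TGF-beta list with a median of 0.03 beside a mean of -0.08. Among other cell types T cell (6 and 18, adjusted p = 0.262), NK cell (11 and 5, adjusted p = 0.149) and erythroid genes (adjusted p = 0.149) did not pass, nor did the rest.

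Of 25652 peaks called after IFNg (30.1%), 12104 were higher (median 0.80) and 13548 lower (-1.18), and 23996 (93.5%) moved the same way in each donor, again among peaks called in these donors. Scaling by total count shifted the median of all peaks by -0.113 (from 0.0115 to -0.102) and split 25112 calls into 8561 higher and 16551 lower. The count was 12099 without donor A, and DESeq2 called 16415.

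**Figure D2:**
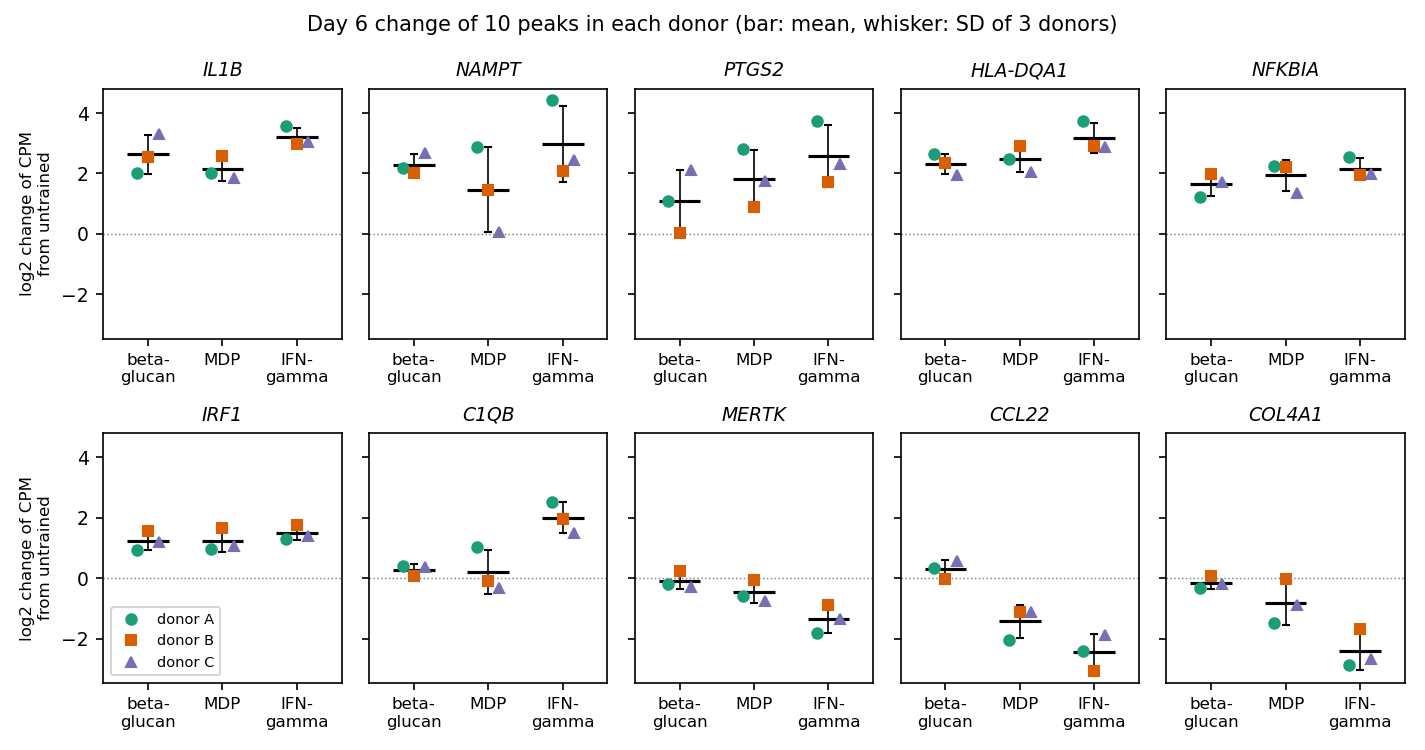
Change of log2 CPM against untrained cells (y axis) at 10 named peaks after beta-glucan, MDP and IFNg, with a point per donor, a bar at the mean and a whisker of 1 SD. NFKBIA is higher after each stimulus in all 3 donors, and CCL22 is lower after MDP and IFNg in all 3.

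Compared directly, beta-glucan and IFNg differed at 13495 peaks (7779 higher after beta-glucan, 5716 lower), MDP and IFNg at 2558 (1557 and 1001), and beta-glucan and MDP at 756 (518 and 238). A peak 16423 bases from CXCL8, the interleukin-8 chemokine gene (chromosome 4, 73723994 to 73724298), stood at 5.00 ± 1.19 CPM after beta-glucan, 6.11 ± 3.08 after MDP and 0.289 ± 0.187 after IFNg (4.19 ± 0.459, adjusted p = 1.16e-06, and 4.43 ± 0.425). GBP5, an interferon-induced GTPase (chromosome 1, 89272630 to 89273143), was lower after beta-glucan (6.71 ± 0.615 CPM) and MDP (6.25 ± 0.552) than after IFNg (15.7 ± 3.11), by -1.26 ± 0.197 and -1.34 ± 0.182. Relative to IFNg, beta-glucan left COPG1 (4.27 ± 0.598), CPQ, SORCS1 and SNX2 (3.94 ± 0.483) higher, and WWC3 (-2.97 ± 0.342), ZNF331, TNKS, SMTNL2 and ZDHHC18 lower. MDP left CAST (3.28 ± 0.444), SNX2, FMN1 and GFOD1 higher than IFNg did, and SRP54 (-2.37 ± 0.403), ZDHHC18, TNKS, VPS53 and PAK5 lower. Between beta-glucan and MDP the largest differences were PAK5 (2.59 ± 0.474), PTPA, TEKT5, TTC39B and RPGRIP1 higher after beta-glucan, and CHN2 (-1.60 ± 0.298), ERN1, the growth factor gene IGF1 (-1.43 ± 0.332), SMTNL2 and the nucleotide receptor gene P2RY6 (-1.29 ± 0.272) lower.

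MHC class II genes were lower than after IFNg with beta-glucan (0 higher, 34 lower peaks, adjusted p = 1.18e-10, and adjusted p = 0.133 with an estimated correlation) and with MDP (0 and 19, adjusted p = 1.88e-14, and adjusted p = 0.0674 with an estimated correlation). So were IFN-gamma response genes with beta-glucan (4 and 27, adjusted p = 6.33e-05, and adjusted p = 0.0903 with an estimated correlation) and MDP (0 and 15, adjusted p = 4.9e-10, and adjusted p = 0.0135 with an estimated correlation). Inflammatory genes were lower with beta-glucan (13 and 54, adjusted p = 0.000935, and adjusted p = 0.403 with an estimated correlation). With MDP they had 8 higher and 18 lower (adjusted p = 0.0069, and adjusted p = 0.516 with an estimated correlation). MDP cells were also below IFNg cells in cholesterol synthesis (2 and 3, adjusted p = 0.0445, and adjusted p = 0.18 with an estimated correlation) and in NK cell genes (1 and 3, adjusted p = 0.00106, and adjusted p = 0.14 with an estimated correlation), where NCAM1 changed by -0.85 ± 0.132. No list passed between beta-glucan and MDP, the lowest adjusted p being 0.0756 for cholesterol synthesis. These counts moved with single donors. Beta-glucan against MDP gave 3 without donor C, 6 without donor A and 1548 without donor B. MDP against IFNg gave 549 without donor C, 1149 without donor B and 1161 without donor A. Beta-glucan against IFNg gave 4760 without donor A and 8309 without donor B. DESeq2 called 263, 1092 and 7535, and scaling by total count made 9285 of 13223 calls between beta-glucan and IFNg higher.

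Many peaks were called with more than 1 stimulus. Beta-glucan and MDP shared 1115 higher and 381 lower calls, against 81 and 32 for independent lists, with 1 call opposite. Beta-glucan and IFNg shared 1157 and 446 (independent 199 and 85; 10 opposite), and MDP and IFNg 4373 and 4662 (698 and 812; 16 opposite). The 3 comparisons share untrained libraries. Simulated unchanged groups gave a covariance of log2 changes across peaks of 0.0565, 0.0569 and 0.0575, and the observed covariance was 0.169, 0.216 and 0.357. The observed correlations, across peaks that are not independent replicates, were 0.663, 0.599 and 0.84 (simulated 0.522, 0.516 and 0.563), and 0.479 and 0.453, 0.464 and 0.46, and 0.699 and 0.709 when each comparison took different untrained libraries. Split that way, fewer calls were shared. Shared higher calls numbered 639 and 547, 758 and 627, and 2807 and 2650. Shared lower calls numbered 221 and 207, 302 and 282, and 3162 and 2876. Across peaks, the correlation of changes between donors A and B, A and C, and B and C was 0.0835, 0.32 and 0.183 for beta-glucan, 0.291, 0.422 and 0.296 for MDP, and 0.525, 0.569 and 0.397 for IFNg. The size of the stimulus effect differed between donors at 384 (beta-glucan), 1331 (MDP) and 1901 (IFNg) of 73924 peaks.

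**Figure D3:**
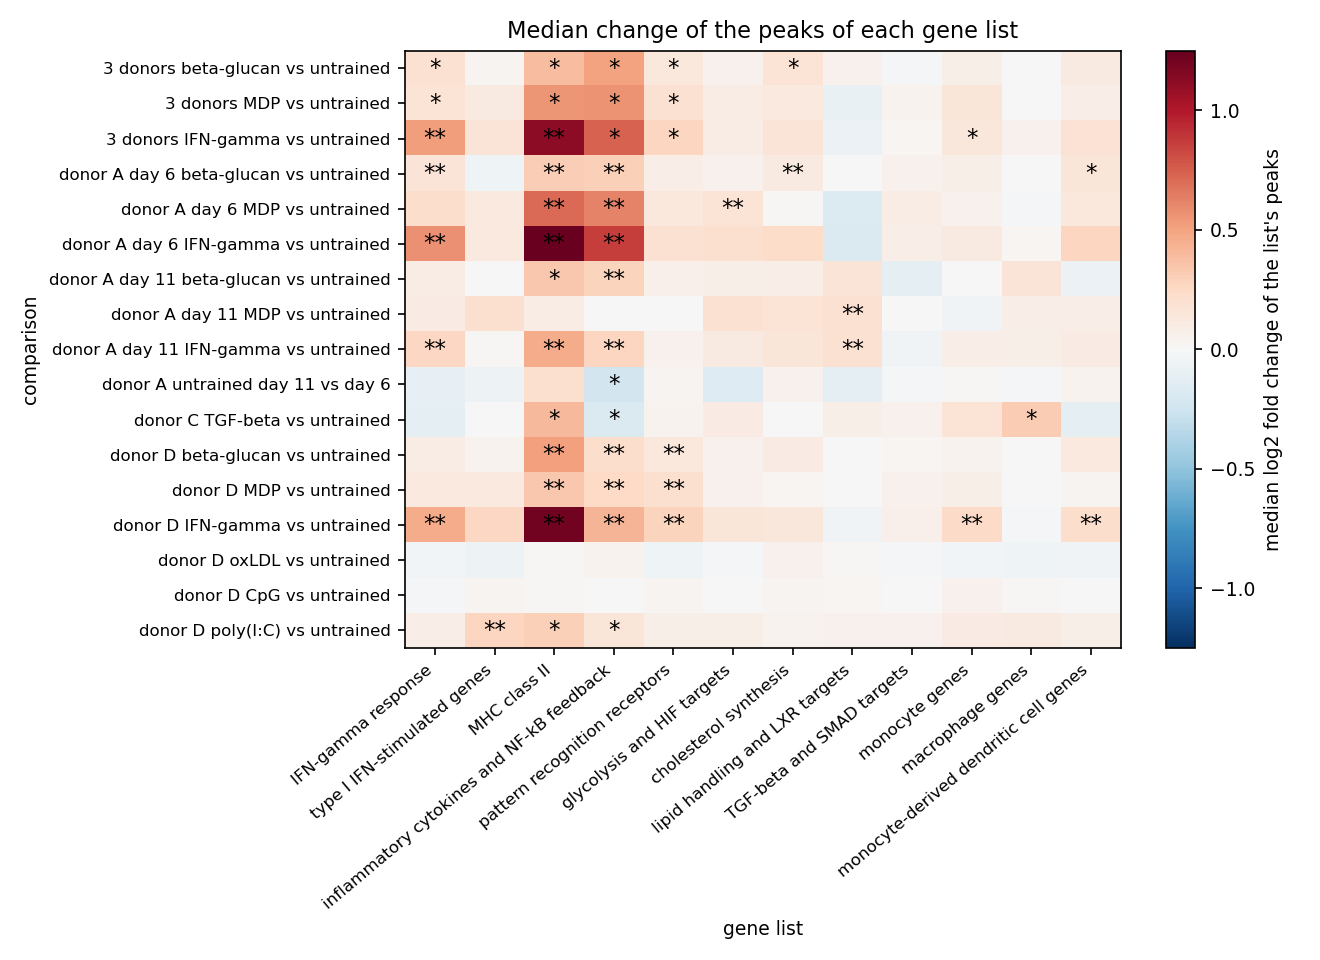
Median log2 fold change (colour) of the peaks of 12 gene lists (x axis) in the 17 comparisons with untrained cells (y axis); * marks a list that passed with the preset correlation and ** one that also passed with an estimated correlation. The MHC class II list reaches 1.12 after IFNg in 3 donors.

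In 3 donors gains and losses lay at different distances from genes. Of peaks higher after IFNg, 25.5% lay within 1 kb of the end of a protein-coding gene, against 14.3% of the other tested peaks (Fisher's exact test, adjusted p = 1.95e-190), and of peaks lower after IFNg only 6.04%. The shares were 20.8% (others 15.6%, adjusted p = 1.78e-20) and 6.02% (others 16.6%, adjusted p = 9.19e-109) after MDP, and 13.4% (others 16%, adjusted p = 0.00997) and 6.02% (others 16%, adjusted p = 6.07e-12) after beta-glucan. Within 2 kb the share of peaks higher after beta-glucan was 19.5% (others 20.1%, adjusted p = 0.638), so that call was lost. Single donors did not all agree. In donor D the shares were 21.4% and 5.97% after IFNg, but 8.7% (others 15.5%, the other way than in 3 donors) and 7.86% after MDP and 11% and 5.91% after beta-glucan. After beta-glucan at day 6 in donor A they were 10.1% and 12.6%. TGFb, given in donor C alone, has no 3-donor shares to be set beside. Its shares were 13.5% and 12.7%, both below the 23.3% of the other tested peaks of donor C (Fisher's exact test, adjusted p = 1.18e-13 and 2.62e-16). These shares were taken with TMM scaling only, and the exact tests treat peaks as independent. At day 6 the most accessible 10% of peaks held more of the counts after IFNg than in untrained cells. This was 55.9% and 55.5% against 51.3% and 49.9% in donor A, 54.1% and 53.6% against 48.3% and 51.5% in B, and 55.3% and 55.2% against 53.7% and 52.7% in C. Whether that moved the shares near gene ends was not tested.

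In donor A at day 6, whose libraries also enter the 3-donor comparison, MHC class II and inflammatory genes rose with each stimulus, with 2 libraries per group. IFNg raised TCOF1 from 3.86 ± 1.40 to 127 ± 14.9 CPM (4.99 ± 0.162), NAMPT from 1.00 ± 0.145 to 27.5 ± 4.22 and SOD2, a mitochondrial superoxide dismutase, from 17.7 ± 1.34 to 149 ± 2.62 (3.06 ± 0.119). No count was left after IFNg at ICA1 (at least 12.2-fold lower), ASB5 (at least 10-fold), COLEC10 (at least 9.1-fold), ZBTB8OS and UBLCP1. MDP raised NFKBIA by 2.29 ± 0.113 and lowered HK3, a hexokinase, by -1.42 ± 0.152; MGST1 and PTPN13 had no count left (at least 4.88-fold lower), and IL2RA, the interleukin-2 receptor alpha chain, had 31 counts against 1 (ratio 27.5, 4.58 to 1120). Beta-glucan raised HLA-DQA1 by 2.80 ± 0.331 and CCR7, a homing receptor of dendritic cells, by 1.91 ± 0.389, and its largest rises were SPSB1 (39 counts against 1, ratio 60.2, 10.2 to 2440), ARHGEF10, LRP5, RBFOX3 and DIP2C. At ARHGEF10 the untrained day 6 libraries held 1 count, against 34 after beta-glucan, 19 after MDP and 25 after IFNg. At LRP5 they held 1, against 29 after beta-glucan and 18 after IFNg, so neither rise is particular to beta-glucan. Calls numbered 4914 (3514 higher), 23928 (11771 higher) and 34145 (16864 higher) of 91738 for beta-glucan, MDP and IFNg. MHC class II and inflammatory genes passed for each stimulus, also with an estimated correlation (the highest adjusted p was 0.0246, for beta-glucan). IFN-gamma response passed for beta-glucan and IFNg (9 and 0, and 53 and 7 peaks, adjusted p = 0.00203 and 3e-07). Cholesterol synthesis passed for beta-glucan (10 and 1, adjusted p = 0.0165), glycolysis for MDP (41 and 19, adjusted p = 0.0139). Dendritic cell genes passed for beta-glucan (6 and 0, adjusted p = 0.0165, and adjusted p = 0.088 with an estimated correlation). The beta-glucan count was 2060 without untrained replicate 1, 2996 without untrained replicate 2, 2368 and 2138 without beta-glucan replicates 1 and 2, and 813 with DESeq2; the MDP count was 15721 without untrained replicate 1. Total-count scaling shifted the median by -0.109 for MDP and -0.16 for IFNg and left 8277 of 23557 and 11775 of 33926 calls higher.

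By day 11 the calls against untrained cells numbered 15434 (8874 higher) for beta-glucan, 12424 (6837) for MDP and 10944 (5931) for IFNg, but many went the other way than at day 6. HLA-DQA1 was still higher after beta-glucan (2.02 ± 0.305) and IFNg (1.86 ± 0.324). Another peak, inside NFKBIA, was higher by 1.10 ± 0.0953 after beta-glucan, JAK2, a kinase of interferon signalling, by 0.69 ± 0.109 after IFNg, and a distal peak of IL6 had 27 counts after IFNg against 3 (ratio 7.94, 2.44 to 40.9). A peak in ABCG1, a cholesterol exporter, was lower after MDP (-3.47 ± 0.305; 2.00 ± 0.241 against 22.2 ± 3.92 CPM) and IFNg (-2.21 ± 0.259). The lipid list as a whole rose in both (40 higher and 3 lower peaks, adjusted p = 0.00127; 27 and 4, adjusted p = 0.0182). MDP left no count at TMEM181 (at least 17.1-fold lower), KLF18, AZU1, DLGAP2 and 1 peak of PRDM16 and raised YTHDF2 (2.67 ± 0.569). HNF4A had 2 counts after beta-glucan against 45 (inverse ratio 32.3, 8.43 to 275), and SCOC 3 after IFNg against 68 (inverse ratio 25.7, 8.42 to 128). MHC class II still passed after beta-glucan (15 higher, 0 lower; median 0.34, adjusted p = 0.000114, and adjusted p = 0.0553 with an estimated correlation) and IFNg (17 and 0; 0.46, adjusted p = 1.36e-08). Inflammatory genes passed after both (55 and 3, adjusted p = 4.78e-07; 39 and 2, adjusted p = 1.52e-05) and IFN-gamma response after IFNg (23 and 3, adjusted p = 8.24e-05). After MDP, MHC class II (2 and 1; 0.774) and inflammatory genes (13 and 6; 0.645) did not pass.

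The untrained day 11 libraries stood apart from all others of donor A: 43% and 41.5% of their counts lay in the most accessible 10% of peaks (47.8% to 57.2% elsewhere) and 31.9% and 31.3% near gene ends (34.9% to 42.8%). Peaks higher at day 11 after beta-glucan, MDP and IFNg lay near gene ends in 55.6%, 47.9% and 53.7% of cases, and the change rose with the mean level across peaks (rank correlation 0.518, 0.46 and 0.438). With offsets that remove that trend the counts were 4936 (1209 higher), 4383 (889) and 4250 (1225), and total-count scaling, which shifted the medians by -0.199, -0.182 and -0.139, gave 14266 (4084), 10553 (2784) and 9451 (2811). Without untrained day 11 replicate 2 they were 7538, 5739 and 3842, without MDP replicate 2 the MDP count was 6561, and without IFNg replicate 2 the IFNg count 4753; DESeq2 called 7270, 5673 and 4432.

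**Figure D4:**
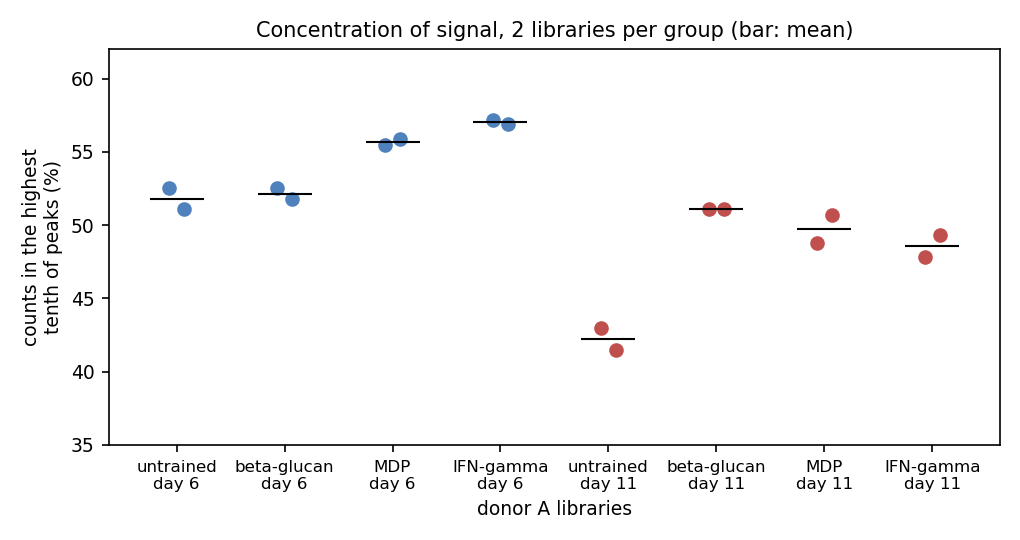
Percent of counts in the most accessible 10% of peaks (y axis) for the 16 libraries of donor A, 2 per stimulus and day (x axis). The untrained day 11 libraries, at 43% and 41.5%, lie below the other libraries, which run from 47.8% to 57.2%.

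Of the peaks called at day 6, 44% kept their sign at day 11 for beta-glucan, 45.4% for MDP and 63.8% for IFNg, and 14.6%, 9.05% and 12.5% were called again in the same direction (35.3%, 10.4% and 4.62% in the opposite one). With trend-removing offsets these were 46.7%, 32.3% and 58.4%, and 8.09%, 0.722% and 4%. The stimulus effect differed between days at 10956, 19518 and 17278 peaks; for beta-glucan the count was 4591 (675 higher) with those offsets, 6417 without untrained day 11 replicate 2, and 8737 (2178 higher) with total-count scaling. The effect of IFNg on MHC class II was lower at day 11 (median -0.91, adjusted p = 1.7e-07), as was that on inflammatory genes (-0.48, adjusted p = 2.95e-06) and IFN-gamma response genes (-0.26, adjusted p = 0.0404). At SOD2 the difference was -2.90 and at HLA-DRA -1.69. At IRF1 it was 2.22, at another peak than that named in 3 donors (chromosome 5, 132441799 to 132442263). There IFNg cells held 72 counts against 322 in untrained cells at day 6, and 147 against 117 at day 11. That difference is a day 6 loss no longer seen at day 11, not a growing gain. MDP's effect was lower on MHC class II (-0.64, adjusted p = 4.7e-05) and inflammatory genes (-0.51, adjusted p = 1.34e-06) and higher on lipid genes (0.38, adjusted p = 0.00125). In untrained cells 22426 peaks differed between days, 10193 higher at day 11; the peak inside NFKBIA fell from 185 ± 10.9 to 79.7 ± 0.744 CPM (-1.22 ± 0.0945), and LRP5 had 42 counts against 1 (ratio 62.3, 10.6 to 2520). Inflammatory genes were lower at day 11 (9 higher, 42 lower, adjusted p = 0.0341, and adjusted p = 0.397 with an estimated correlation). That count was 11363 (6821 higher) with trend-removing offsets, 22775 (16797 higher) with total-count scaling, which shifted the median by 0.245, 12871 without untrained day 11 replicate 2 and 14278 without untrained day 6 replicate 1.

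TGFb, tested in donor C alone, moved chromatin the other way at inflammatory genes, although the list missed the threshold with an estimated correlation (adjusted p = 0.167 with an estimated correlation). The peak inside NFKBIA was lower than in untrained cells (-0.71 ± 0.103; 139 ± 0.156 against 227 ± 18.4 CPM, n = 2 libraries), and MARCO, a scavenger receptor of macrophages, higher (1.04 ± 0.19; 54.2 ± 15.4 against 27.7 ± 3.80 CPM). Peaks at the collagen genes COL18A1 (24 counts against 1, ratio 43, 7.01 to 1770) and COL6A2 (17 against 2, ratio 15.2, 3.61 to 136) were among the largest rises, with AKAP1 and TMEM170B. IL2RA had no count left (at least 2.79-fold lower), nor had CCDC13 (4.28), SERPINA1 (3.54), RCAN3 and UXS1. In the inflammatory list 14 of 149 peaks were lower and 1, at CCL20, higher (median -0.18, adjusted p = 0.00324, and adjusted p = 0.167 with an estimated correlation). Macrophage genes had 8 higher, at APOE, CTSD, MARCO and MERTK, and 1 lower (18 and 5 adjusted over the list alone, median 0.32, adjusted p = 0.00209, and adjusted p = 0.167 with an estimated correlation). MHC class II had 3 higher of 40, at CIITA and HLA-DQB1 (median 0.41, adjusted p = 0.00209, and adjusted p = 0.167 with an estimated correlation). The TGF-beta and SMAD target list itself did not pass (17 higher, 12 lower, adjusted p = 0.687). TGFb changed 1918 of 48108 peaks (943 higher, 975 lower). That count was 603 and 999 without TGFb replicates 1 and 2, 1115 and 985 without untrained replicates 1 and 2, and 283 with DESeq2.

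Against the 3 other stimuli in donor C, TGFb cells had lower accessibility at the peak outside NFKBIA (38.2 ± 11.9 CPM, against 240 ± 29.4 after beta-glucan, 180 ± 17.5 after MDP and 283 ± 7.38 after IFNg; -2.73 ± 0.142, -2.32 ± 0.144 and -2.97 ± 0.142). ICAM1 was lower than after beta-glucan (-2.51 ± 0.227) and IFNg (-2.57 ± 0.232), CD80 likewise (-2.74 ± 0.338 and -1.99 ± 0.25), and RIPK2, the kinase that relays NOD2 signals, lower than after beta-glucan (-2.80 ± 0.395). Peaks at macrophage genes were higher (as a list, adjusted p = 0.141, 0.214 and 0.209 with an estimated correlation), such as CTSD against beta-glucan (1.88 ± 0.231), APOE against MDP (1.32 ± 0.177; 62.2 ± 6.81 against 25.3 ± 0.142 CPM) and MERTK against IFNg (1.31 ± 0.196). PRSS23 had 29 counts against none after IFNg (at least 12-fold higher), and TNFAIP8 none against 34 after beta-glucan (at least 7.05-fold lower). Inflammatory genes had 4 higher and 64 lower peaks against beta-glucan (adjusted p = 9.55e-15), 6 and 56 against MDP (1.48e-12) and 8 and 63 against IFNg (3.57e-13), and passed with an estimated correlation each time (0.0173, 0.0252 and 0.0226). Macrophage genes had 20 and 3, 20 and 2, and 15 and 6 (adjusted p = 0.000593, 0.00112 and 0.00945, adjusted p = 0.141, 0.214 and 0.209 with an estimated correlation), and dendritic cell genes 1 and 13, 1 and 12, and 2 and 18 (adjusted p = 0.00532, 0.00566 and 0.000631, adjusted p = 0.0743, 0.076 and 0.0318 with an estimated correlation). IFN-gamma response was lower against beta-glucan (3 and 15, adjusted p = 0.0143, and adjusted p = 0.112 with an estimated correlation) and IFNg (3 and 20, adjusted p = 0.000315). MHC class II was lower against IFNg (1 and 16, adjusted p = 7.18e-05). Pattern recognition receptors were lower against beta-glucan (2 and 15, adjusted p = 0.03, and adjusted p = 0.28 with an estimated correlation). They were also lower against IFNg (1 and 23, adjusted p = 0.000933, and adjusted p = 0.101 with an estimated correlation). Lipid genes were higher against MDP (16 and 3, adjusted p = 0.0405, and adjusted p = 0.235 with an estimated correlation). Calls numbered 4920, 4300 and 6375 (1196, 786 and 1926 with DESeq2). Without TGFb replicate 1 they were 1943, 1534 and 3004; other libraries that moved a count over 1.5-fold were beta-glucan replicate 2 (3084), TGFb replicate 2 (2730), MDP replicates 1 and 2 (2767 and 2520) and IFNg replicate 2 (3673).

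Donor D, in a table of its own, gained accessibility at MHC class II and inflammatory genes with beta-glucan, MDP and IFNg. MMP12, a macrophage elastase (chromosome 11, 102879872 to 102880138), had no count in untrained cells and 36 after beta-glucan, 45 after MDP and 129 after IFNg (at least 11.3, 13.8 and 69.5-fold higher, n = 2 libraries each). IFNg raised HLA-DQA1 from 0.315 ± 0.176 to 17.9 ± 1.08 CPM (5.61 ± 0.386) and CD74 from 21.2 ± 1.91 to 110 ± 1.98 (2.36 ± 0.121). A different CXCL8 peak was higher after beta-glucan (2.54 ± 0.293; 9.72 ± 0.299 against 1.60 ± 0.377 CPM), and FABP4, a fatty acid carrier, lower (-3.79 ± 0.479). IRAK2, an adaptor kinase of Toll-like receptor signalling, was higher after MDP (1.37 ± 0.179) and IFNg (2.13 ± 0.177), VNN1 and VAC14 rose after each of the 3, and IFNg left no count at SH3BGRL2 (at least 19.8-fold lower), MGST1 (14.2), RAB38, C8A and ITSN1. Calls numbered 8358 (4362 higher) for beta-glucan, 8637 (4389) for MDP and 29933 (14740) for IFNg of 94167. MHC class II had 21 higher and 1 lower, 12 and 0, and 48 and 0 peaks (26 and 1, 14 and 1, and 52 and 0 adjusted over the list alone), with adjusted p = 2.04e-10, 1.57e-06 and 1.18e-18. Inflammatory genes had 42 and 9, 44 and 6, and 83 and 24 (adjusted p = 0.000341, 1.57e-06 and 1.09e-05). Pattern recognition receptors had 16 and 2, 18 and 2, and 45 and 14 (adjusted p = 0.0473, 0.00365 and 0.00521). These lists passed with an estimated correlation as well. IFNg raised IFN-gamma response (53 and 5, adjusted p = 2.66e-06). It also raised monocyte (27 and 5, adjusted p = 0.00785), dendritic cell (40 and 18, adjusted p = 0.0222) and NK cell genes (15 and 1 of 55, adjusted p = 0.00521, and adjusted p = 0.033 with an estimated correlation for the last 3), with NCAM1 at 1.91 ± 0.159. Without 1 library the beta-glucan count was 3716 and 4972 (untrained replicates 1 and 2) and 5348 and 5035 (beta-glucan replicates 1 and 2), the MDP count 3860 and 5163 (untrained) and 3860 and 4955 (MDP), and the IFNg count 19919 (IFNg replicate 2); DESeq2 called 1816, 1837 and 15847.

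PolyIC raised antiviral genes in donor D. CMPK2, an interferon-induced nucleotide kinase, rose by 1.89 ± 0.357 (6.24 ± 0.44 against 1.84 ± 0.897 CPM), TNFAIP3 by 1.03 ± 0.135 and CD74 by 0.74 ± 0.141. The largest rises were VNN1 (16 counts against 2, ratio 12.7, 2.99 to 114), ETV6 (3.27 ± 0.552), PRKCH, PRDM16 and DEPTOR, and ANKRD13B (at least 8.38-fold lower) and FER1L6 (7.12) had no count left. Type I IFN-stimulated genes had 15 higher and 1 lower of 84 peaks (17 and 2 adjusted over the list alone), with 7 of 28 genes only higher, 1 with both and 20 with no call (median 0.26, adjusted p = 0.000779, and adjusted p = 0.0158 with an estimated correlation). MHC class II (8 and 0, adjusted p = 0.0186) and inflammatory genes (21 and 6, adjusted p = 0.0333) passed with the preset correlation only (adjusted p = 0.124 with an estimated correlation for both). PolyIC changed 8313 peaks (3781 higher, 4532 lower), 1897 and 5463 without polyIC replicates 2 and 1, 4295 and 5016 without untrained replicates 1 and 2, and 2142 with DESeq2.

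OxLDL and CpG left few calls in donor D. OxLDL changed 22 peaks (19 higher), with TGFA, an epidermal growth factor family ligand, at 4.06 ± 0.39 against 0.956 ± 0.265 CPM (2.14 ± 0.445), ENTPD8, FOXL3, UNC5A and DEGS2 (1.21 ± 0.177) higher and TDRD6 (-1.16 ± 0.199), SLC48A1 and TSPOAP1 lower. CpG changed 11, all higher, led by UNC5A (1.16 ± 0.183; 41.9 ± 13.1 against 18 ± 4.4 CPM), TMEM132A, PLAC9, PDE2A and PRRT1B (0.96 ± 0.196). No list passed for either. DESeq2 called 0 for both, while at an unadjusted p below 0.05 edgeR gave 5005 peaks for oxLDL and 4145 for CpG, where chance alone gives 4708. Without 1 library the oxLDL count was 9 (oxLDL replicate 2, where only 2 were higher and the balance turned, or untrained replicate 1) or 69 (oxLDL replicate 1), and the CpG count 1 (CpG replicate 1 or untrained replicate 2), 2 (untrained replicate 1) or 24 (CpG replicate 2). Peaks that differed among any of the 6 stimuli of donor D numbered 36540.

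**Figure D5:**
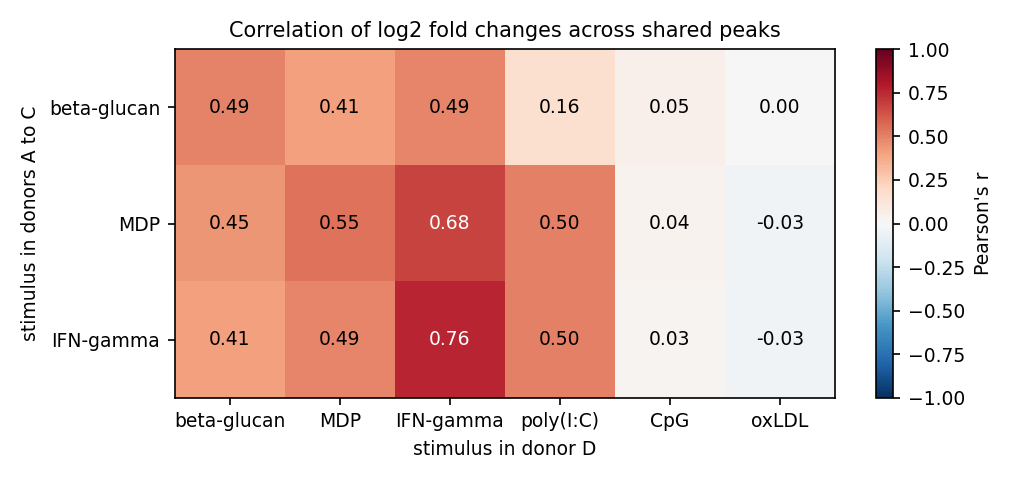
Correlation across 71746 shared peaks (colour, number in each cell) between log2 fold changes against untrained cells in 3 donors (y axis) and in donor D (x axis). It is 0.493 for beta-glucan, 0.545 for MDP and 0.76 for IFNg, and near 0 between IFNg and oxLDL (-0.0336) or CpG (0.0258).

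The 3-donor comparison and donor D share no library, so donor D tests its calls separately. Over 71746 peaks that overlap by 50% both ways, changes correlated at 0.493 for beta-glucan, 0.545 for MDP and 0.76 for IFNg across peaks, which are not independent replicates. Of the 3-donor calls, 1466 of 1518 (96.6%), 7970 of 8917 (89.4%) and 21367 of 22722 (94%) had the same sign in donor D. For beta-glucan and MDP the agreement was not particular to the stimulus. The 3-donor beta-glucan changes correlated at 0.489 with donor D's IFNg, where 95% of the calls had the same sign (92.2% with its MDP) and 79.3% were called again, against 59% with its beta-glucan. Shares called again also depend on the number of calls, which in donor D was 31.8% of tested peaks after IFNg and 8.88% after beta-glucan. The MDP changes correlated more with donor D's IFNg (0.678) than with its MDP, and IFNg calls had the same sign after polyIC in 77.5% of cases, after CpG in 50.2% and after oxLDL in 47.3%.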

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

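Of the explanations tested here, those on signal in the untrained day 11 libraries, on IFNg against MDP and on depth were chosen after the results they explain were seen. What flagged each result in the next 3 paragraphs is a tested difference of the stimulus effect between the 2 days of donor A, or between donors. Of the 3 patterns weighed after them, the 2 in donor D come from no such test.

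The effect of beta-glucan in donor A differed between days at 10956 peaks. Among named peaks the difference (day 11 minus day 6, log2) was 2.99 at SCLT1, 2.88 at PRAG1 and 2.88 at TIMM23. Where a group held 1 to 3 counts it was taken from the counts, with an exact 95% interval: SEC63 4.02 (1.17 to 9.41), HPF1 3.73 (0.787 to 9.14), ARHGEF10 -8.79 (-14.1 to -5.69), HNF4A -8.22 (-11.5 to -5.57), PTPRN2 -8.25 (-13.6 to -5.12), TMEM175 -7.73 (-11 to -5.14) and LRP5 -7.7 (-13 to -4.77). The effect of MDP differed at 19518 peaks, by 4.83 at SAFB and, from such counts, 5.44 (2.69 to 10.8) at EXOC6B, -8.76 (-13.9 to -4.95) at ARHGEF10 and -8.4 (-13.6 to -4.87) at PRDM16. This PRDM16 peak (chromosome 1, 3379368 to 3379716) kept 1 count after MDP at day 11 and is not the one left with none. With no count in 1 group only a bound can be given, from a floor of 3 counts over the group: at least 3.05 higher at PTPN13, 2.67 at MGST1 and 1.7 at CLPTM1, and at least as low as -5.93 at AZU1, -5.49 at DLGAP2 and -4.73 at KLF18. From its list results came HLA-DOA (-1.13), IL1RN (1.77) and SCD (1.57), and medians of -0.64 for MHC class II, -0.51 for inflammatory genes and 0.38 for lipid handling. All these differences also hold the change of untrained cells between days. From day 6 to day 11, IL1RN went from 888 to 915 counts after MDP and from 1461 to 394 in untrained cells. SCD went from 619 to 929 and from 980 to 445, and HLA-DOA from 694 to 305 and from 247 to 213. These counts are not scaled for depth, which was lower at day 11, so they do not show how far each group changed. Total counts per untrained library were 5.76 M and 4.57 M at day 6, and 2.83 M and 3.06 M at day 11. After MDP they were 6.05 M and 6.5 M, and 3.98 M and 4.37 M.

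The effect of IFNg differed at 17278 peaks. The difference was at least 2.67 at ASB5, 2.51 at COLEC10, 2.37 at UBLCP1, 2.26 at PTPRR and 2.19 at ICA1, and at least as low as -4.55 at ZNF331. From 1 to 3 counts it was -6.88 (-12.2 to -3.78) at IL2RA, -6.83 (-12.2 to -3.71) at LRP5, -6.81 (-12.2 to -3.82) at ARHGEF10 and -6.53 (-9.93 to -3.67) at KRT17. From its lists came IRF1 (2.22), HLA-DRA (-1.69), SOD2 (-2.90) and LIPA (2.14), and medians of -0.26 for IFN-gamma response, -0.91 for MHC class II, -0.48 for inflammatory genes and 0.31 for lipid handling. The IRF1 peak had 72 counts after IFNg against 322 in untrained cells at day 6, and 147 against 117 at day 11. The ARHGEF10 differences of each stimulus rest on the same untrained counts, 1 at day 6 and 41 at day 11. Those at LRP5 do too (1 and 42).

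Between donors A, B and C the effect differed at 384 peaks for beta-glucan, 1331 for MDP and 1901 for IFNg. Leaving out the library farthest from its replicate, donor B IFNg replicate 1, gave 816, 2358 and 2360.

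The first pattern is the number of calls at day 11 in donor A. Of the 15434 beta-glucan calls, 4099 (26.6%) stayed called with offsets that remove the trend of change with signal, and both untrained day 11 libraries held a smaller share of counts in the most accessible 10% of peaks (43% and 41.5%) than the other 14. That fits lower signal over background in those 2 libraries as a source of most of the calls, although a real change in untrained cells between days could look alike. Without the untrained libraries, 634 peaks were called between IFNg and beta-glucan at day 11 with those offsets, so some peaks did differ, but the number lies between the limits set beforehand and only 45.6% of their day 6 calls had the same sign, which leaves open how far this is a remaining difference. Between IFNg and MDP 2440 were called, and 76.7% of their day 6 calls had the same sign, which fits a remaining difference in these 2 libraries per group of 1 donor, while 4623 were called between MDP and beta-glucan, with only 29.5% of the same sign.

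The second pattern is the few calls after CpG (11) and oxLDL (22) in donor D. Lower depth is excluded, as these libraries averaged 6.03 M counts, 1.3 times the 4.65 M of the IFNg libraries with 29933 calls. A small change in the direction of the other stimuli cannot be told. Among peaks called with IFNg the CpG and IFNg changes had a covariance of 0.16, above the 0.112 to 0.122 of simulated unchanged groups, but oxLDL gave 0.0951, below its simulated lowest value of 0.11. Among peaks called with polyIC, CpG gave 0.211, above the simulated 0.173 to 0.191, and oxLDL 0.169, within 0.164 to 0.198. So CpG lay above its simulated range both times and oxLDL did not. Since oxLDL fell below its range among IFNg calls, the simulated groups may not span real unchanged ones. Lying outside the range therefore decides nothing by itself. For CpG the question also stays open because 3-donor IFNg calls had the same sign in only 50.2% of cases.

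The third pattern is the rise of the NK cell list after IFNg in donor D. Without NCAM1 the median log2 change of the other 42 peaks was 0.417, and 71.4% were higher, which falls between what was set for NK cells in those libraries and for none, so the test cannot tell. The 4 called peaks of TBX21 (of 5; median 1.18) and 5 of GNLY (of 8; 0.686) were higher, as was 1 each of EOMES (0.534) and NCR1 (0.323), while 1 of NCR3 was lower and none was called at PRF1 (0.682), KLRD1, KLRF1, GZMB or SH2D1B (-0.917 to -0.158). A change at NCAM1 alone is excluded, since called peaks of TBX21 and GNLY were higher too. The 13 NCAM1 peaks had a median of 0.068, below that of the other 42, the result set beforehand against NCAM1 as the source. That median does not show NCAM1 unchanged, as 4 of its peaks were called, all higher.

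For the 3-donor comparisons, all 10 splits of the 6 summed libraries into 3 and 3 were fitted. Splits were made without regard to donor. Some put both summed libraries of a donor on 1 side and so, unlike the real grouping, mix the contrast with donor. The real grouping gave the most calls each time (1 of 10): 1934 against at most 170 for beta-glucan, 10007 against 6 for MDP, 25652 against 0 for IFNg, 756 against 1 for beta-glucan and MDP, 13495 against 0 for beta-glucan and IFNg, and 2558 against 17 for MDP and IFNg. With 10 splits, no share under 0.05 can be reached.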

How the results depend on the processing

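The fits without the library of lowest depth, without the library farthest from its replicate, with peaks assigned to the nearest gene end, and between stimuli within donor A were chosen after the results were seen. No named called peak and no called list changed sign under any setting, but the balance of higher and lower calls did turn. With loess offsets the calls higher at day 11 went from 57.5% to 24.5% (beta-glucan), 55% to 20.3% (MDP) and 54.2% to 28.8% (IFNg), for untrained day 11 against day 6 from 45.5% to 60% and for the beta-glucan interaction from 51.1% to 14.7%. Total-count scaling turned these as well (28.6%, 26.4%, 29.7%, 73.8% and 24.9%), with the MDP interaction (53.5% to 47.1%), TGFb against MDP (45.6% to 53.1%; 50.6% with loess) and IFNg (42.8% to 52.1%), and donor D beta-glucan (52.2% to 43.8%) and MDP (50.8% to 42.5%). The 1.2-fold test gave 48.7%, 39.4% and 38% at day 11 and 38.9% for the beta-glucan interaction, and a fit of only the groups compared 47.9% (MDP) and 45.1% (IFNg). In 3 donors MDP went from 49% to 63.9% without a donor covariate, 57.4% without donor A and 53.8% with DESeq2, and MDP against IFNg from 60.9% to 49.6% with limma-voom. OxLDL went from 86.4% to 22.2% without oxLDL replicate 2. Within donor A, IFNg against beta-glucan at day 11 went from 318 of 901 to 386 of 634 with loess, and with total-count scaling IFNg against MDP from 1073 of 2422 to 1355 of 2430 at day 11 and from 3612 of 6828 to 2888 of 6971 at day 6. Other turns began near an even split. Most counts kept within 1.5-fold are not listed, and the cause of the changes below was not tested, except where a setting has fewer samples or a stricter test by its own construction. In simulated data most changes under 2-fold were missed. Within donors, n is 2 libraries, and where 1 is left out the lone library is assumed to vary like the other groups. Pairs of libraries with the same number do not pair: correlations of replicate differences ran from -0.0792 to 0.0854. Not run were the GC offset and the motif tests, including those in a 200-base window, for want of a genome.

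DESeq2 (Wald test) called fewer peaks throughout: beta-glucan 1062, MDP 4784, IFNg 16415, beta-glucan against MDP 263, beta-glucan against IFNg 7535 and MDP against IFNg 1092 in 3 donors. In donor A it called 813, 8803 and 17412 at day 6 and 7270, 5673 and 4432 at day 11. It called 5058, 7324 and 5699 for the day interactions and 10273 for untrained day 11 against day 6. TGFb gave 283 against untrained, 1196 against beta-glucan, 786 against MDP and 1926 against IFNg. In donor D it called 1816, 1837, 15847, 0 for oxLDL, 0 for CpG, 2142 for polyIC and 16844 for any stimulus. A test against a 1.2-fold change gave 723 for beta-glucan, 5048 for MDP, 44 between them, 7660 for beta-glucan against IFNg and 763 for MDP against IFNg. In donor A it gave 2886 for beta-glucan at day 6 and 9523, 7202 and 5519 at day 11. TGFb gave 912, 3216 against beta-glucan and 2585 against MDP. Donor D gave 4391, 4574, 11 for oxLDL, 2 for CpG and 4490 for polyIC.

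In 3 donors, without a donor covariate the counts were 53, 471, 11668, 0 between beta-glucan and MDP, 1842 and 45. In that fit edgeR called 0, while the unadjusted count in the fit with donor was 12030 and DESeq2 called 263. With 24 unsummed libraries they were 4925 (beta-glucan), 15691 (MDP), 4573 (between them) and 7553 (MDP against IFNg). Limma-voom gave 5743, 19532, 5056, 20413 (beta-glucan against IFNg) and 7696. The replicate block gave 4221 (beta-glucan), 3760 (against MDP) and 6542 (MDP against IFNg). With only the groups compared they were 3739 (beta-glucan), 2294 (against MDP) and, in donor D, 34 for CpG. Loess offsets gave 4936, 4383 and 4250 at day 11, 4591 for the beta-glucan interaction, 11363 for untrained day 11 against day 6 and 17 for CpG, and total-count scaling 17 for CpG.

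Leaving out 1 donor, or donor B IFNg replicate 1 (the library farthest from its replicate), gave these ranges in 3 donors: beta-glucan 107 to 2209, MDP 2294 to 10596, IFNg 12099 to 24671, beta-glucan against MDP 3 to 1548, beta-glucan against IFNg 4760 to 13009, MDP against IFNg 549 to 2641. Without the library of lowest depth, IFNg gave 25216 and beta-glucan against IFNg 13600. Leaving out 1 library within donors gave, in donor A, day 6 beta-glucan 2060 to 2996 and MDP 15721 to 16844, day 11 beta-glucan 7538 to 12198, MDP 5739 to 10973 and IFNg 3842 to 8833, beta-glucan interaction 6417 to 10708 and untrained day 11 against day 6 12871 to 18500. TGFb gave 603 to 1115, against beta-glucan 1943 to 3491, against MDP 1534 to 2767, against IFNg 3004 to 4695. Donor D gave beta-glucan 3716 to 5348, MDP 3860 to 5163, IFNg 19919 to 24214, oxLDL 9 to 69, CpG 1 to 24 and polyIC 1897 to 5463. The donor interaction went from 384, 1331 and 1901 to 816, 2358 and 2360.

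At 2 kb in place of 1 kb, the share near gene ends was 19.5% of peaks higher with beta-glucan (13.4% at 1 kb; the call was lost), 19% of MDP against IFNg calls (14.1%; lost). It was 18.4% of peaks higher in the MDP interaction (14.7%; gained), 18.4% of those lower in the IFNg interaction (12.6%; lost), and 26.4% and 26.6% of those lower with TGFb than with MDP and IFNg (20.8% and 20.6%; lost). With loess offsets 46.7%, 32.3% and 58.4% of day 6 calls kept their sign at day 11 (44%, 45.4% and 63.8%), and 8.09%, 0.722% and 4% were called again (14.6%, 9.05% and 12.5%).

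Of 468 list tests 82 passed, 91 with peaks near gene ends, 107 with 1 peak per gene, 79 with the nearest gene end, 83 with loess offsets and 56 with an estimated correlation. Of the 82, these settings lost 28 (near gene ends), 24 (1 peak per gene), 6 (nearest gene end), 4 (loess) and 36 (estimated correlation). Among list tests that had not passed, 99 changed direction with 1 peak per gene and 91 with peaks near gene ends. Under both settings some of these then passed, in the other direction than in the main fit. In 3 donors 22 passed, 17 without donor A, 24 without donor B and 24 without donor C, and within donors 60, with 59 in the replicate block. DESeq2 ended the call at 134 of 406 named pairs of peak and comparison, the 1.2-fold test at 32, while the fit without a donor covariate kept 76 of those it tested and ended 78. Leaving out 1 donor or library at a time kept 1554 calls and ended 216. The RLE factors and the fit without a filter, which tested all 406, ended none, nor did the unsummed libraries, which tested 137, or the replicate block, which tested 252 within donors and 137 in 3 donors.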

Other observations

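The comparisons below, between stimuli within donor A, were chosen after the results were seen. At day 11 IFNg cells had less accessibility than beta-glucan cells at FN1, the fibronectin gene (-2.06 ± 0.239; 4.49 ± 0.653 against 19.1 ± 1.32 CPM, n = 2 libraries, adjusted p = 1.29e-09), at NRDE2 (-2.40 ± 0.389) and at the distal peak of CXCL8 (-2.86 ± 0.547; 0.694 ± 0.648 against 4.85 ± 1.98 CPM). TLN1, which encodes the integrin adaptor talin, was lower after IFNg than after MDP (-2.86 ± 0.345; 1.61 ± 1.06 against 12.5 ± 1.46 CPM). IFIT3, an interferon-induced gene, was higher after MDP than after beta-glucan (3.24 ± 0.61; 4.13 ± 1.32 against 0.401 ± 0.262 CPM). Calls at day 11 numbered 901 for IFNg against beta-glucan (318 higher), 2422 for IFNg against MDP (1073 higher) and 4327 for MDP against beta-glucan (2365 higher). With loess offsets they numbered 634 (386 higher), 2440 and 4623, and total-count scaling gave 832 (486 higher) for the first.

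MHC class II genes were higher after IFNg than after MDP at day 11 (14 higher, 0 lower; median 0.43, adjusted p = 2.89e-10; adjusted p = 0.0162 with an estimated correlation), as were inflammatory genes (18 and 3; adjusted p = 5.63e-05; adjusted p = 0.0889 with an estimated correlation). MDP cells were below beta-glucan cells in MHC class II (0 and 9; median -0.34, adjusted p = 9.81e-06) and inflammatory genes (4 and 46; median -0.26, adjusted p = 8.64e-07), each with adjusted p = 0.0537 with an estimated correlation. No list passed between IFNg and beta-glucan at day 11. At day 6 the counts were 22243, 6828 and 12622 for IFNg against beta-glucan, IFNg against MDP and MDP against beta-glucan. WWC3 (3.71 ± 0.258; 35.9 ± 5.58 against 2.78 ± 0.396 CPM) and ETV6 (2.81 ± 0.296) were higher after IFNg than after beta-glucan, and ZDHHC18 (2.87 ± 0.256) than after MDP. MHC class II was higher after IFNg than after beta-glucan (39 and 1; adjusted p = 6.25e-14) and MDP (27 and 0; adjusted p = 3.59e-17), and NK cell genes than after MDP (7 and 0; adjusted p = 0.000654; adjusted p = 0.0214 with an estimated correlation). MDP cells were above beta-glucan cells at day 6, the other way than at day 11, in inflammatory genes (53 and 9; adjusted p = 1.97e-05; adjusted p = 0.0616 with an estimated correlation) and MHC class II (7 and 2; adjusted p = 0.00928; adjusted p = 0.0955 with an estimated correlation). Of the day 6 calls, 40.1%, 74.9% and 29% had the same sign at day 11.

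Within donor D, beta-glucan and MDP shared 2516 higher and 2134 lower calls (203 and 180 for independent lists), and IFNg and polyIC 2298 and 3283 (592 and 731). These comparisons share untrained libraries. The controls were not split, as each part would keep only 1 library, so part of the excess may come from the shared controls. DESeq2 called 1816 (beta-glucan), 1837 (MDP), 15847 (IFNg) and 2142 (polyIC) peaks. Unchanged simulated groups gave a covariance of 0.0527 for beta-glucan and MDP, against 0.222 observed, and 0.0524 for IFNg and polyIC, against 0.325.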
